A study of Mus musculus with 6 samples.

How the data were processed

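Poly-A RNA of mouse bone marrow cells sorted as LT-HSCs was made into stranded paired-end libraries and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. The samples were 3 libraries from saline-treated and 3 from carnosine-treated mice, all irradiated with 5.0 Gy. Groups and replicate numbers were taken from the sample titles. CASAVA 1.8, HISAT2, StringTie, edgeR and the genome build GRCm38 are named, with no roles, in the submitters' processing notes. The step each tool was used for, the annotation, the treatment of reads that fit several genes and the use of strand in counting are not given in the sources used here. Reads shared by similar genes or by overlapping and antisense genes may therefore be split in ways that the values cannot show.

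The deposited table holds, for each of 53465 genes, a count and an FPKM value per library, per the file headers. The deposited counts are whole numbers that are not normalized, and 27982 genes had at least 1 count in some library. The deposited FPKM values equal the count divided by a gene length and by the library's own total count, checked on genes with a mean count of at least 100. The table gives gene symbols, identifiers and positions, and 96.2% of the identifiers lie at the position that the GENCODE M21 annotation of GRCm38 gives. Every row named a gene, and every per-sample column was used.

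Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 15533 genes with 99.8% of all counts, library sizes were scaled by TMM, and carnosine was compared with saline by the quasi-likelihood F-test with no covariate, with p-values adjusted by Benjamini-Hochberg at 0.05. Levels are CPM on the TMM scale, given as mean ± SD of 3 libraries per group. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The biological coefficient of variation was 0.0999. Replicates were compared before averaging: the median squared difference of 2 libraries of a group was 1.79 to 2.11 times sampling noise, against 13.1 to 15.5 between groups, so no libraries were counted as duplicates. Where a gene had 0 counts in a group, the fold is a lower bound against 3 counts summed over that group, and bounds and intervals cover counting error only.

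A total of 37 gene lists with 911 different genes, covering processes, stem and progenitor cells and markers of other cell types, was fixed before the data were examined, as were the design and most alternatives. All lists had at least 5 tested members, and 4 of the symbols were not found in the table. They were tested with camera from limma 3.58.1 on ranked statistics of log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists. Intervals of list medians come from 10000 bootstrap draws of their members. Named genes follow a rule fixed in advance: the 10 largest changes in each direction with adjusted p under 0.05, at least 5 CPM in the higher group, no overlap between groups and a named symbol, and up to 4 members per list by p-value. It adds 12 genes of the gate, damage response and carnosine handling, and the genes with the 5 smallest p-values. Members named because 5 or fewer of a list moved in a direction, and rises outside antibody genes, were chosen after their values were seen. Some genes that the rule names are not reported here.

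The procedure was tested on counts simulated from the means, spreads and library sizes of these libraries for 15533 genes. For carnosine against saline, 74 of 100 genes changed 2-fold and 17 of 100 genes changed 1.3-fold were recovered, all in the right direction. Of the 105 genes called, 14 had not been changed, 13.3% where 5% is aimed at, and with no change at all 1 gene was called. In the data 39.4% of the genes were called, a far larger share than was changed in the simulation. Recovery and the false share may therefore differ in the data. Of the simulated lists changed 1.3-fold, 5 of 5 were called and 0 of 20 unchanged ones. The simulated genes varied independently, while estimated correlations in the real lists reached 0.32. The 0 of 20 therefore cannot show false calls that come from members moving together. A simulated GC trend produced 3390 calls, which the correction for GC content and length brought to 2.

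Alternatives were DESeq2 size factors, upper quartile scaling, no filter, a filter of at least 5 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, and limma-trend on log2(FPKM + 1) for genes of at least 1 FPKM in 3 libraries. Further ones were the replicate number as a block, a fold change of at least 2, and each library left out in turn. For lists they were camera with an estimated correlation and fry. A correction for GC content and gene length (natural splines of 5 degrees of freedom per library, as offsets), leaving out genes with unstable counts and leaving out antibody genes were added after seeing the data. Alternatives planned for a table without counts were not needed.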

Results

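Gene expression was measured by RNA sequencing in cells sorted from mouse bone marrow as long-term haematopoietic stem cells (LT-HSCs). Such cells divide rarely and give rise to all blood lineages. Wild-type mice had received 5.0 Gy of radiation over the whole body, and afterwards either saline or carnosine, a dipeptide of beta-alanine and histidine that is abundant in muscle. The sort kept cells without lineage markers that carried Sca-1 (encoded by Ly6a) and c-Kit (Kit) and lacked Flk2 (Flt3) and CD34 (Cd34). Each group had 3 libraries, 6 in all, and every mouse group was irradiated. The total count per library ran from 12602067 to 16866534 in the saline group and from 12730837 to 13651553 in the carnosine group. The labels do not say whether the 3 libraries of a group came from separate mice, so p-values here measure only the spread between these libraries, which may be technical. The comparison asks which transcripts differ in the sorted cells of irradiated mice given carnosine in place of saline.

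The libraries of a group were close to each other and apart from those of the other group. Across the tested genes, which are not independent replicates, Pearson's r of log2 CPM (counts scaled to library size) was 0.988 to 0.990 within groups and 0.959 to 0.962 between them, and the first principal component, with 67.4% of the variance, separated the groups. Mitochondrially encoded genes took 5.16 ± 0.0161% of the counts in the saline group and 4.64 ± 0.0188% in the carnosine group (SD, n = 3 each). The exact two-sided permutation test gave p = 0.10 for that share, the smallest value that 3 against 3 libraries allow. It gave 0.10 also for the share of the 50 most abundant genes, 12.7 ± 0.0800% against 12.3 ± 0.0470% (SD, n = 3 each). Total counts (exact permutation p = 0.40) and the number of genes detected (exact permutation p = 0.60) overlapped between the groups.

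Transcripts of Flt3 and Cd34, whose proteins the sort excluded, and of Mki67, a gene of dividing cells, were abundant in both groups, while the stem cell gene Procr was low. These levels are at odds with rarely dividing cells that lack both markers. They are transcripts, however, while the sort read surface proteins, and no library came from an unirradiated mouse. The label LT-HSC therefore names the gate here, not a checked identity. Kit was at 329.6 ± 10.2 CPM with saline and 378 ± 4.11 CPM with carnosine (SD, n = 3 each), a log2 fold change of 0.20 ± 0.0284 (SE). Flt3 was at 210.3 ± 8.64 and 179.9 ± 2.51 CPM, and fell (log2 fold change -0.22 ± 0.0351, SE). Cd34, at 329 ± 19 and 301 ± 4.7 CPM, lay at the threshold of edgeR's quasi-likelihood test (log2 fold change -0.13, Benjamini-Hochberg adjusted p = 0.0502), and passed in 4 of its 12 alternative settings. Among these, Cd34 had an adjusted p of 0.0086 without saline replicate 3, 0.04 with at least 5 CPM in 3 libraries and 0.017 with the GC and length correction (edgeR; range 0.0086 to 0.14 over its alternatives). Ly6a, at 30.2 ± 8.13 and 29.2 ± 8.79 CPM, varied more within each group than between them (log2 fold change -0.0579 ± 0.247, SE). Its sign turned when saline replicate 1 or carnosine replicate 1 or 2 was left out (0.19, 0.0881 and 0.0325). The sort required its protein, Sca-1, yet both levels lay far below those of Kit, the other required marker. Procr, which encodes the endothelial protein C receptor carried by stem cells, was low in both groups (5.66 ± 0.219 and 4.97 ± 0.418 CPM) and did not pass the test (adjusted p = 0.27). Mki67 was at 1012 ± 9.88 CPM with saline and 1099 ± 8.24 CPM with carnosine (log2 fold change 0.12 ± 0.0191, SE).

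Carnosine libraries had lower levels of immediate early and megakaryocyte genes and higher levels of myeloid progenitor genes (median log2 fold changes -1.13, -1.32 and 0.95; camera adjusted p = 2.2e-12, 3.6e-08 and 8.4e-08). With an estimated correlation, camera's adjusted p-values were 0.049, 0.035 and 0.035. Of 15533 genes tested, 3038 were higher and 3077 lower with carnosine (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes made up 475 of the rises and 549 of the falls. The 2 groups of libraries did not overlap for 52.3% of the tested genes, where chance gives 10%. The orphan nuclear receptor Nr4a1 (ENSMUSG00000023034, chromosome 15, 101266846 to 101274792, GRCm38) had the smallest p-value, falling from 881 ± 1.53 to 159.8 ± 3.8 CPM (SD, n = 3 each). Next came Fosl2, a partner of Jun in the AP-1 transcription factor (-3.10 ± 0.0362 on the log2 scale, SE), the antibody constant region Ighg2b (5.42 ± 0.0733), the histone demethylase Kdm6b (-2.04 ± 0.0291) and the transcriptional repressor Bhlhe40 (-2.19 ± 0.0335). With limma-trend on the deposited FPKM values, the split moved to 3387 genes higher and 2156 lower of 13348.

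Among genes of at least 5 CPM in the higher group, the 10 largest rises were in variable (V) segments of antibody genes. Igkv12-38 (chromosome 6, 69943186 to 69943648, GRCm38), Igkv5-43 (chromosome 6, 69823355 to 69823943) and Ighv8-12 (chromosome 12, 115647945 to 115648387) had 0 counts in the 3 saline libraries, which allows a level of up to 0.0679 CPM by counting error. They reached 36 ± 1.08, 26.2 ± 1.0 and 24.7 ± 1.11 CPM in the carnosine libraries (SD, n = 3). Against a floor of 3 counts over the saline group they were at least 531, 386 and 364 times higher. The other 7 of the 10 largest rises, Ighv1-85, Igkv3-4, Ighv2-2, Igkv6-14, Ighv9-2, Igkv4-57-1 and Ighv1-49, were likewise at 0 in every saline library, with lower bounds from 87.6 to 236. V segments resemble each other, and how reads shared between them were counted is not given in the sources used here, so each segment's level is uncertain. Outside antibody genes, in a set chosen after the values were seen, the largest rises were Trnp1 (3.44 ± 0.207 on the log2 scale, SE), the granulocyte transcription factor Cebpe (3.12 ± 0.182), Prom1 (3.03 ± 0.342) and Olr1 (2.85 ± 0.221). The counts of Prom1 lay over 2-fold apart between libraries of a group.

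Among the 10 largest falls, those outside V segments were Fosl2, given above, and the genes that follow, which were not tested as a group. Adamts1, a secreted protease, fell from 10.4 ± 0.407 to 0.635 ± 0.458 CPM, the matrix protein gene Cyr61 from 7.15 ± 1.32 to 0.435 ± 0.243 CPM. Thrombospondin 1 (Thbs1, chromosome 2, 118111876 to 118127133, GRCm38) fell from 78.1 ± 2.04 to 7.98 ± 0.255 CPM (SD, n = 3 each). The scavenger receptor Stab2 (-3.23 ± 0.118 on the log2 scale, SE), the potassium channel regulator Abcc9 (-3.41 ± 0.238) and the neutrophil granule gene Ltf (-3.08 ± 0.123) completed the set, with the V segments Igkv8-34, Ighv3-8 and Ighv1-11. Igkv8-34 had 0 counts in the carnosine libraries and was at least 84.4 times lower there, against a floor of 3 counts over the carnosine group. Ighv3-8 had 1 count there and 381 with saline, a ratio of 351 (95% counting interval 62.6 to 13898), and Ighv1-11 had 2 against 272, a ratio of 125 (34.3 to 1040).

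Immediate early genes, which cells switch on within minutes of a stimulus, fell nearly throughout. Of 28 members, 27 fell and 1, Myc, rose, with the same counts when adjusted over the list alone, and the median log2 fold change was -1.13 (bootstrap 95% interval -1.45 to -0.84; camera adjusted p = 2.2e-12). Egr1 (chromosome 18, 34859823 to 34864984, GRCm38) fell from 917 ± 24.4 to 341 ± 4.07 CPM and Junb from 811 ± 17.6 to 325 ± 4.37 CPM (SD, n = 3 each), while Myc rose from 104 ± 3.17 to 167 ± 3.58 CPM. Genes of NF-kB and the inflammatory response fell with them: 22 of 30 members fell and 2 rose (Vcam1 and Traf1), 23 and 2 when adjusted over the list alone, with a median of -1.17 (-1.45 to -0.82; camera adjusted p = 5.1e-08). Tumour necrosis factor (Tnf) fell from 62.8 ± 2.18 to 12.4 ± 0.594 CPM, the chemokine gene Cxcl2 from 46.5 ± 1.34 to 8.51 ± 0.589 CPM. The inhibitor Nfkbia fell from 588 ± 16.9 to 254 ± 8.41 CPM and the mRNA decay factor Zfp36 from 908 ± 19 to 461 ± 4.05 CPM. Of the 30 NF-kB members 11 stand in another list, and Zfp36 belongs to the immediate early list too.

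Genes of TGF-beta and SMAD signalling, a pathway tied to stem cell dormancy, were lower in 14 of 20 cases and higher in 1 (Id2), the same when adjusted over the list alone (median -0.38, -0.95 to -0.25; camera adjusted p = 5.7e-05). The co-receptor Tgfbr3 fell from 134 ± 2.47 to 59.6 ± 2.65 CPM and the repressor Ski from 87.9 ± 1.62 to 52.7 ± 1.54 CPM (SD, n = 3 each). Id1 fell (-1.31 ± 0.065 on the log2 scale, SE) while its relative Id2 rose (0.92 ± 0.0495). Of 14 senescence-associated genes, 9 fell and 0 rose (12 and 0 adjusted over the list alone; median -1.27, -2.01 to -0.30; camera adjusted p = 1.5e-05). That call was lost with an estimated correlation (adjusted p = 0.19), and 9 of the members stand in other lists too. Vegfa, an inducer of vessel growth, fell from 106 ± 6.83 to 30.4 ± 1.1 CPM and the adhesion molecule Icam1 from 67.1 ± 2.52 to 35.6 ± 1.3 CPM.

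Targets of p53, the transcription factor that radiation activates, split. Cdkn1a, which arrests the cell cycle (ENSMUSG00000023067, chromosome 17, 29090979 to 29100722, GRCm38), fell from 182 ± 2.27 to 40.4 ± 3.53 CPM (SD, n = 3 each; log2 fold change -2.18 ± 0.0618, SE; adjusted p = 7.5e-07, edgeR). The pro-apoptotic Bbc3 fell from 36.6 ± 1.34 to 12.2 ± 0.737 CPM, Plk2 from 54.6 ± 2.96 to 10.4 ± 0.201 CPM. The p53 inhibitor Mdm2 fell from 98.8 ± 1.52 to 66.4 ± 2.14 CPM and Btg2 from 152 ± 0.937 to 86.8 ± 4.17 CPM. Bax, the pore-forming death effector, was at 42.7 ± 5.45 and 42.4 ± 5.7 CPM and did not pass the test (log2 fold change -0.00983 ± 0.124, SE; adjusted p = 0.96, edgeR). The sign of Bax turned without saline replicate 1 (0.0927) or carnosine replicate 1 (0.0977) and with the GC and length correction (0.12). In the whole list 10 of 32 members fell and 8 rose (11 and 8 adjusted over the list alone), and the list was not called (camera adjusted p = 0.60). The members that rose are not among those named above, and log2 fold changes in the list ran from -2.40 to 0.79. Of the 32 members 11 stand in other lists too, such as Btg2 among the immediate early genes. The median of the p53 list, 0.0059, was above 0, while its mean of -0.23 and the direction of camera were below.

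Genes that repair double-strand breaks rose modestly. Of 36 members 17 rose and 0 fell, the same when adjusted over the list alone, with a median log2 fold change of 0.24 (0.14 to 0.27; camera adjusted p = 9.4e-05). The call was lost with an estimated correlation (adjusted p = 0.06). Rad50, part of the complex that binds broken ends, rose from 149 ± 3.42 to 177 ± 1.72 CPM. The Fanconi anaemia genes Fanca and Fancd2 rose from 69.5 ± 1.05 to 87 ± 2.98 and from 45.2 ± 2.26 to 60.2 ± 2.94 CPM (SD, n = 3 each). In base and nucleotide excision repair 6 of 25 members rose, among them Neil3 (0.42 ± 0.0528 on the log2 scale, SE) and Xpc (0.38 ± 0.0498). A further 3 fell (Ung, Polb and Parp1), the same counts over the list alone (median 0.039; camera adjusted p = 0.55). Of 22 pro-apoptotic genes 7 rose, such as Fadd (0.53 ± 0.0642) and Bak1 (0.22 ± 0.0318), and 4 fell (among them Bbc3, Bcl2l11 and Tnfrsf10b), the same over the list alone. That list was not called (median 0.090, mean -0.047; camera adjusted p = 0.54, upward). Of 18 anti-apoptotic genes 9 fell, including Mcl1 (501 ± 9.51 to 289 ± 5.68 CPM) and Pim1 (685 ± 6.03 to 389 ± 11.3 CPM). The 3 that rose were Bcl2a1d, Bcl2a1b and Bcl2a1a, near-identical copies whose shared reads leave each uncertain. The counts were 9 and 4 over the list alone. It was not called either (median -0.085, mean 0.068; camera adjusted p = 0.20, downward), but passed with a filter of at least 5 CPM in 3 libraries (camera adjusted p = 0.0098, with a range of 0.0098 to 0.40 over its camera alternatives).

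Genes of the G2 and M phases rose. 31 of 35 members rose and 1 fell (Cdc25b), 32 and 1 when adjusted over the list alone, with a median log2 fold change of 0.42 (0.33 to 0.52; camera adjusted p = 2.4e-12). Cyclin B1 (Ccnb1) rose from 31.5 ± 1.06 to 52 ± 0.115 CPM, the spindle gene Hmmr from 62 ± 2.35 to 113 ± 2.95 CPM and the cytokinesis gene Anln from 50.2 ± 1.51 to 87.7 ± 0.535 CPM (SD, n = 3 each). Genes of G1/S and DNA replication moved both ways: 11 of 39 fell, such as Orc1 (-0.53 ± 0.0736 on the log2 scale, SE), and 6 rose, such as Rrm2 (0.57 ± 0.0327), the same over the list alone. This list was not called (median 0.012, mean -0.012; camera adjusted p = 0.73, downward). Cell cycle inhibitors and quiescence factors fell in 14 of 21 cases and rose in 3 (Gfi1, Rbl1 and Rbl2; Gfi1 counts lay over 2-fold apart within a group), the same over the list alone (median -0.41, -1.05 to -0.21; camera adjusted p = 0.0018). The call was lost with an estimated correlation (adjusted p = 0.068). Of the 21 tested members 5 stand in other lists too, among them Nr4a1, Egr1 and Cdkn1a, which fell.

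Long-term stem cell genes were mostly lower with carnosine: 22 of 33 fell and 3 rose (Sult1a1, Gprc5c and Clca3a1), 23 and 3 when adjusted over the list alone (median log2 fold change -0.78, -0.93 to -0.19; camera adjusted p = 5.5e-05). With an estimated correlation the list missed the threshold (adjusted p = 0.051). The transcription factor Gata2 fell from 357 ± 4.18 to 197 ± 4.97 CPM. Von Willebrand factor (Vwf, chromosome 6, 125546774 to 125686679, GRCm38) fell from 107 ± 3.7 to 30.5 ± 0.759 CPM and the cytokine signalling inhibitor Cish from 84.3 ± 2.46 to 18 ± 0.273 CPM (SD, n = 3 each). Megakaryocyte genes, a list that shares members with the stem cell list such as Vwf, fell in 16 of 18 cases and rose in 0 (17 and 0 over the list alone; median -1.32, -1.73 to -0.77; camera adjusted p = 3.6e-08). They included the integrin Itga2b (208 ± 9.1 to 101 ± 4.28 CPM) and Rab27b (33.2 ± 1.71 to 9.63 ± 0.257 CPM). Adhesion and niche retention genes fell in 10 of 19 cases and rose in 4 (among them Kit, Vcam1 and Itgam), 12 and 4 over the list alone (median -0.23, -0.47 to 0.019; camera adjusted p = 0.034, and adjusted p = 0.14 with an estimated correlation). The angiopoietin receptor Tek fell from 35.2 ± 2.22 to 10.6 ± 1.15 CPM.

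Myeloid progenitor genes rose: 18 of 20 rose and 1 fell (Csf1r), 18 and 2 when adjusted over the list alone, with a median log2 fold change of 0.95 (0.56 to 1.13; camera adjusted p = 8.4e-08). Myeloperoxidase (Mpo, chromosome 11, 87793581 to 87804413, GRCm38) rose from 2757 ± 4.97 to 5404 ± 136 CPM. Neutrophil elastase (Elane, chromosome 10, 79886247 to 79888215) rose from 227 ± 8.32 to 741 ± 13.8 CPM and cathepsin G (Ctsg) from 370.2 ± 2.13 to 835 ± 2.64 CPM (SD, n = 3 each). The receptor Csf1r fell from 84.3 ± 4.36 to 47.8 ± 1.64 CPM. Multipotent progenitor and lymphoid priming genes went both ways, with 7 of 19 higher, such as Irf8 (0.45 ± 0.0363 on the log2 scale, SE), and 7 lower, such as Tcf7 (-1.34 ± 0.089). Over the list alone 7 rose and 9 fell (median -0.13; camera adjusted p = 0.63).

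**Figure D1:**
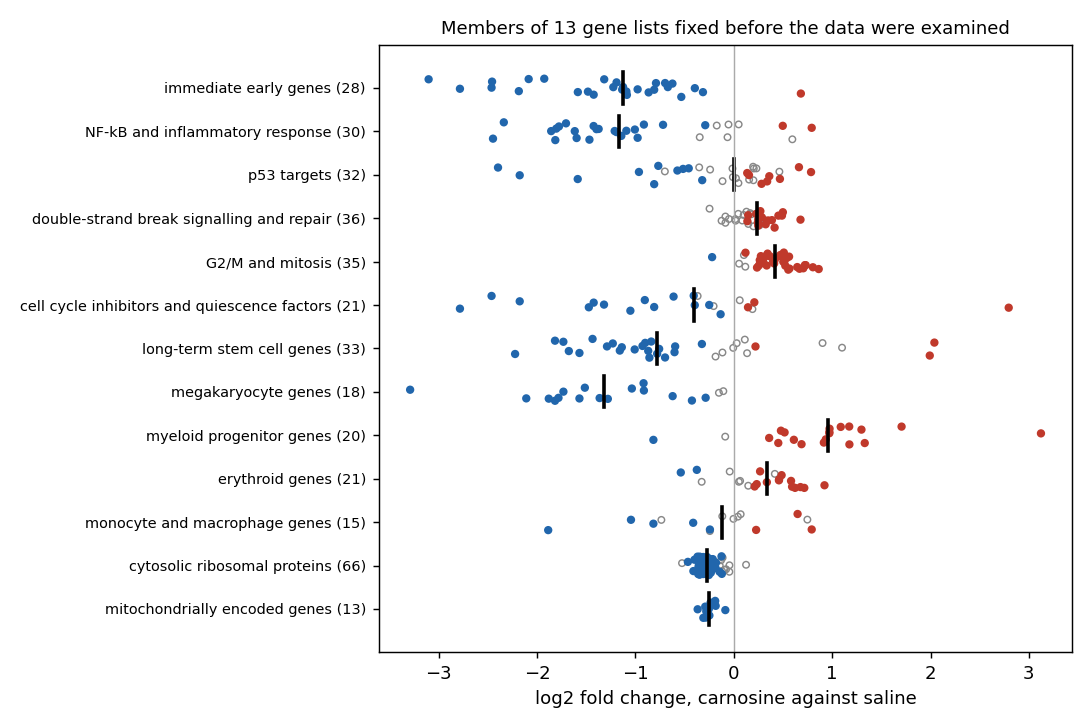
Log2 fold changes (horizontal axis, carnosine against saline, positive where higher with carnosine) of the tested members of 13 gene lists, whose number stands in brackets. Filled points passed the adjusted p of 0.05 over all genes (red higher, blue lower), open points did not, and black bars are list medians, from -1.32 for megakaryocyte genes to 0.95 for myeloid progenitor genes.

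**Figure D2:**
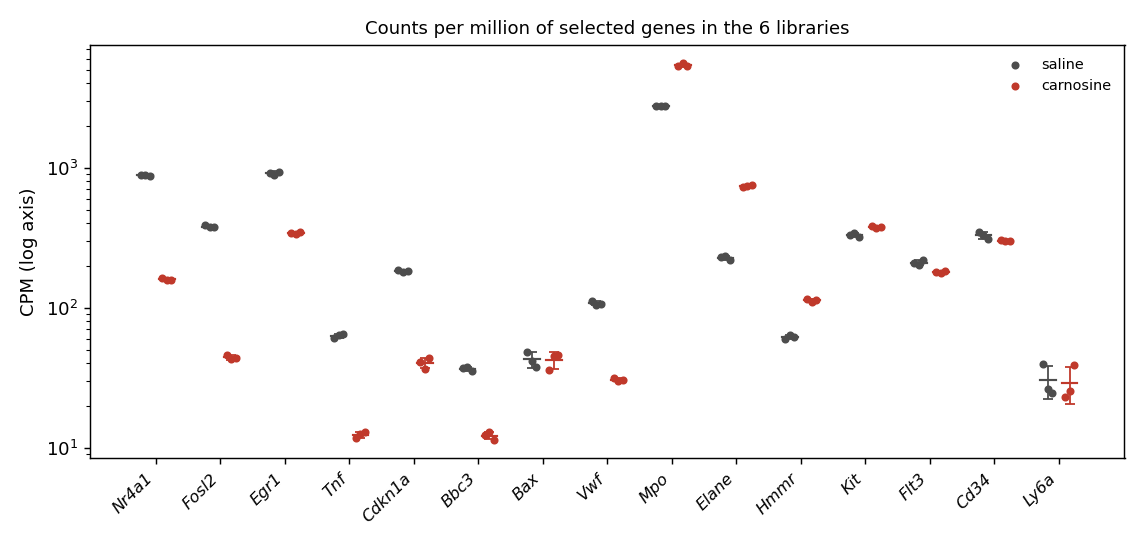
CPM (vertical log axis) of 15 genes in the 6 libraries, with each group's mean as a horizontal line and its SD as an error bar (n = 3). The points of Bax and Ly6a overlap between saline and carnosine, while the 3 carnosine points of Nr4a1 average 159.8 CPM, all below the saline points, which average 881 CPM.

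Erythroid genes rose in 13 of 21 cases and fell in 2 (among them Slc4a1), the same when adjusted over the list alone (median 0.34, 0.15 to 0.49; camera adjusted p = 5.1e-04, and adjusted p = 0.06 with an estimated correlation). Carbonic anhydrase 1 (Car1) rose from 305 ± 2.85 to 428 ± 7.88 CPM and the Rhesus-associated gene Rhag from 60.6 ± 3.07 to 115 ± 3.16 CPM (SD, n = 3 each). Stromal and endothelial genes fell in 9 of 13 cases and rose in 2 (Flt1 and Alpl), 10 and 2 over the list alone (median -1.05, -2.76 to -0.16; camera adjusted p = 0.0041, and adjusted p = 0.12 with an estimated correlation). Most were low, such as Sparc (7.55 ± 0.705 to 0.986 ± 0.154 CPM) and Kdr (7.79 ± 0.858 to 1.47 ± 0.421 CPM). Neutrophil genes were not called: 6 of 16 rose, including Lcn2 (8.8 ± 0.563 to 26.9 ± 1.87 CPM), and 4 fell (Ltf, Ngp, S100a9 and Il1b), 7 and 7 over the list alone. The median was -0.045 and the mean -0.13, both below 0, and camera pointed upward (adjusted p = 0.74). Monocyte and macrophage genes were not called, with 3 of 15 higher (Slc40a1, Vcam1 and Cd68) and 5 lower (among them Csf1r, Mrc1, Lyz2 and Cd14), 4 and 6 over the list alone (median -0.12; camera adjusted p = 0.49). Mast cell, basophil and eosinophil genes rose in 5 of 17 cases (Prg2, Epx, Hdc, Prg3 and Ear2) and fell in 7, the same over the list alone (median -0.23; camera adjusted p = 0.54). Prg2 rose from 10.0 ± 0.703 to 31.3 ± 1.68 CPM while Prss34 fell from 28.3 ± 0.824 to 7.93 ± 0.152 CPM. T and NK cell genes rose and fell equally, 6 and 6 of 20, the same over the list alone (median -0.064; camera adjusted p = 0.75). Gzmb was lower (31.8 ± 1.12 to 11 ± 1.26 CPM) and Nkg7 higher (81.5 ± 1.54 to 114 ± 4.19 CPM).

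B cell genes, which the lineage gate should exclude, were abundant in part. The antibody light chain Igkc rose from 1126 ± 8.02 to 2002 ± 14.2 CPM while the heavy chain of IgM, Ighm, fell from 692 ± 16.1 to 281 ± 3.07 CPM. The class II invariant chain Cd74 rose from 339 ± 9.43 to 909 ± 18.7 CPM (SD, n = 3 each). Of 20 members 8 rose and 3 fell (Ighm, Ms4a1 and Blk), the same when adjusted over the list alone, and the list missed the threshold (median 0.37, 0.016 to 0.95; camera adjusted p = 0.052). It passed in 7 of the 12 alternative settings other than fry, among them those without saline replicate 3, without carnosine replicate 1 and without carnosine replicate 3 (camera adjusted p = 0.045, 0.046 and 0.04, with a range of 0.017 to 0.16 over those 12 settings). Antibody V segments took 0.181 to 0.184% of the counts in saline libraries and 0.343 to 0.346% in carnosine libraries. Of 171 tested V segments 123 rose and 29 fell.

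**Figure D3:**
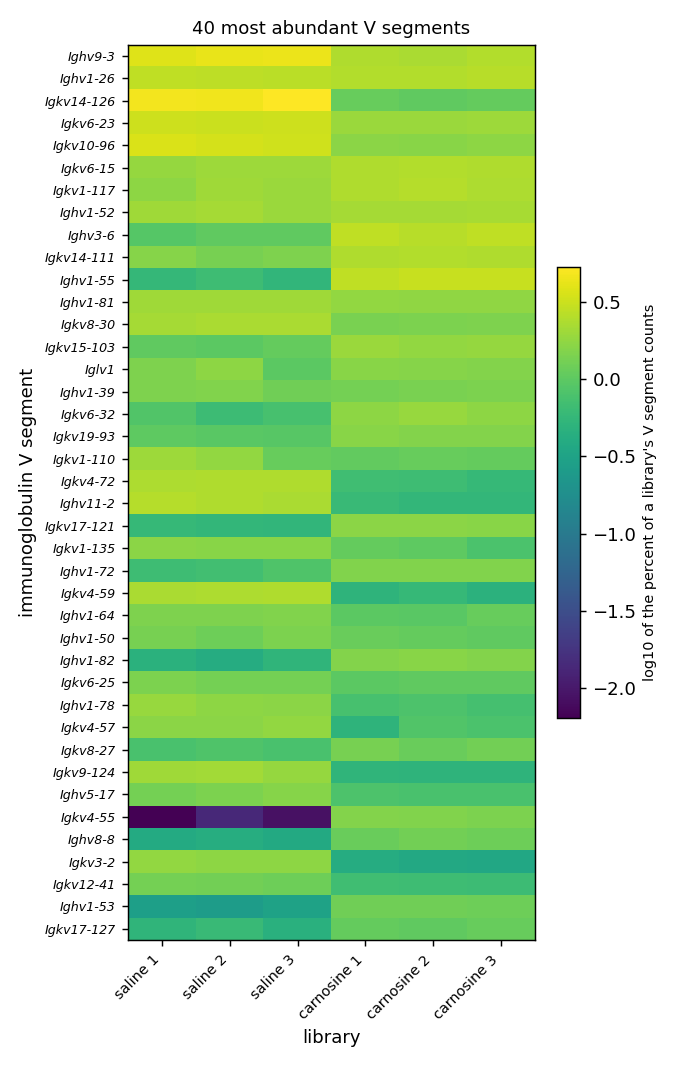
Share of each of the 40 most abundant antibody V segments (rows) in the V segment counts of each of the 6 libraries (columns), as log10 of the percent. Columns of a group look alike and the groups differ: Igkv4-55 holds 0.00645 to 0.0138% in the 3 saline libraries and 1.41 to 1.53% in the 3 carnosine libraries.

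Ribosomal and mitochondrially encoded transcripts were slightly lower. Of 66 cytosolic ribosomal protein genes 52 fell and 0 rose, 53 and 0 when adjusted over the list alone (median log2 fold change -0.27, -0.29 to -0.25; camera adjusted p = 1.4e-13). Ribosomal protein genes have many processed copies, so their levels are uncertain. Rps24 fell from 373 ± 6.73 to 269.6 ± 9.03 CPM and Rpl10a from 612 ± 1.21 to 493 ± 7.21 CPM (SD, n = 3 each). All 13 mitochondrially encoded genes fell, over all genes and over the list alone (median -0.25, -0.28 to -0.20; camera adjusted p = 8.4e-08), though the call was lost with an estimated correlation (adjusted p = 0.13). The cytochrome b gene mt-Cytb fell from 5069 ± 7.96 to 4174 ± 51 CPM. Nuclear-encoded oxidative phosphorylation genes were not called: 10 of 46 fell, such as Atp5g3 (-0.25 ± 0.0365 on the log2 scale, SE), and 1, Ndufs1, rose, 6 and 1 over the list alone (median -0.043; camera adjusted p = 0.10). Myc targets and ribosome biogenesis genes rose in 13 of 29 cases, such as Wdr12 (0.32 ± 0.0329) and Polr1b (0.26 ± 0.0309). They fell in 4 cases (Ddx21, Fbl, Odc1 and Hspe1), the same over the list alone (median 0.072; camera adjusted p = 0.025, and adjusted p = 0.13 with an estimated correlation). That call also ended without saline replicate 2 (camera adjusted p = 0.051, with a range of 0.013 to 0.13 over its camera alternatives).

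Among metabolic and stress lists, genes of autophagy and lysosomes were called, with 12 of 26 lower and 2 higher (Atg12 and Wipi1). The counts were the same when adjusted over the list alone (median log2 fold change -0.18, -0.34 to -0.017; camera adjusted p = 0.019, and adjusted p = 0.12 with an estimated correlation). Ulk1, the kinase that starts autophagy, fell from 102 ± 2.28 to 71.6 ± 1.65 CPM (SD, n = 3 each). Antioxidant and Nrf2 target genes were not called: 14 of 36 rose, such as glutathione reductase (Gsr, 128 ± 1.03 to 214 ± 0.889 CPM) and Mt2 (27.4 ± 0.55 to 52.5 ± 1.08 CPM). The 9 that fell included Ftl1 (-0.30 ± 0.0298 on the log2 scale, SE). The counts were 15 and 9 over the list alone (median 0.050; camera adjusted p = 0.36). Genes producing reactive oxygen species rose in 5 of 12 cases (Mpo, Ncf1, Ncf4, Cyba and Rac1) and fell in 2 (Ptgs2 and Alox5). The counts of Rac1 lay over 2-fold apart within a group. The list had 6 and 2 over the list alone (median 0.071; camera adjusted p = 0.39). Glycolysis genes rose in 7 of 22 and fell in 2, the glucose transporters Slc2a1 and Slc2a3, the same over the list alone (median 0.0065; camera adjusted p = 0.36). Hypoxia-inducible factor targets rose in 5 of 25 and fell in 7, such as Ddit4 (-0.96 ± 0.0545), the same over the list alone (median -0.0061; camera adjusted p = 0.55). Type I interferon genes rose in 6 of 33, such as Mx1 (1.14 ± 0.0948), and fell in 5 (Ifitm3, Irf9, Bst2, Parp14 and Oas1a), 5 and 5 over the list alone (median 0.031; camera adjusted p = 0.54).

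Genes of the unfolded protein and integrated stress responses divided: 13 of 24 rose, such as the chaperone gene Calr (2062 ± 7.84 to 2645 ± 31.2 CPM; SD, n = 3 each). The 7 that fell included the stress transcription factors Atf3 (99 ± 7.28 to 35.4 ± 0.893 CPM) and Atf4 (454 ± 6.23 to 327 ± 9.9 CPM). Over the list alone 13 rose and 8 fell, and the list was not called (median log2 fold change 0.21, mean -0.0043; camera adjusted p = 0.19, upward). Genes that handle carnosine and histidine were not called, with 5 of 14 higher (Hars, Hdc, Hnmt, Slc6a6 and Hrh2) and 4 lower (Slc15a2, Slc15a4, Gadl1 and Slc15a3), the same when adjusted over the list alone (median 0.053; camera adjusted p = 0.74). Cndp2, which encodes a carnosine-cleaving dipeptidase, was at 63.6 ± 0.636 CPM with saline and 62.6 ± 2.48 CPM with carnosine, a log2 fold change of -0.0239 ± 0.0456 (SE; edgeR adjusted p = 0.71). The sign of Cndp2 turned without carnosine replicate 3 (0.00991) and with the GC and length correction (0.00819). The oligopeptide transporter genes Slc15a2 and Slc15a4 fell from 22.5 ± 0.815 to 16.5 ± 1.15 and from 24.9 ± 2.05 to 18.2 ± 1.16 CPM. Ferroptosis and iron genes rose in 8 of 18 cases, such as the transferrin receptor Tfrc (0.23 ± 0.0273 on the log2 scale, SE), and fell in 3 (Ptgs2, Ftl1 and Fth1), the same over the list alone (median 0.11; camera adjusted p = 0.35). Of the 17 lists that camera called with its preset correlation, 7 held with an estimated one: G2/M, myeloid progenitor, megakaryocyte, NF-kB, immediate early, ribosomal protein and TGF-beta genes. They held narrowly: camera's adjusted p was 0.035 for each of the first 4 and 0.049 for each of the last 3.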

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

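The tests with a GC and length correction, without genes of unstable counts and without antibody genes were chosen after the data were seen; the others were planned, and alternatives meant for a table without counts did not apply. Counts of genes higher and lower stayed within 1.5 times the reported ones in every setting except a fold change of at least 2, which by construction left 475 and 549. Leaving out 1 library gave 2491 to 2590 higher and 2591 to 2727 lower. DESeq2 gave 2194 and 2409 (with 10316 adjusted p-values missing by its own filter). limma-trend on FPKM gave 3387 and 2156, and the GC and length correction gave 4 genes a call opposite to the reported one. An estimated correlation left 7 of 17 lists (2 higher, 5 lower), and fry, which does not compare a list with other genes, called 33 (12 and 21). The cause was not tested for the calls lost with an estimated correlation. Leaving out 1 library gave 16 to 18 lists. With the replicate number as a block, 2552 genes were higher, 2679 lower and 18 lists called, with the B cell list (camera adjusted p = 0.046) and Cd34 (edgeR adjusted p = 0.048) gaining the call. The pairing of equal numbers had correlations of 0.00791, 0.0268 and 0.0210, against -0.0250 to 0.0036 for unequal numbers. All are weak, but each library correlates best with its own number, so whether the numbers pair the libraries stays undecided. Of 185 named genes, 160 kept call and direction in all settings run, up to 12 per gene, and 20 called ones lost the call in at least 1 (Alpl, Blk, Bst2, Cd14, Cd68, Cdc25b, Clca3a1, Ear2, Gadl1, Gpx1, H2-Eb2, Hspe1, Oas1a, Odc1, Parp1, Polb, Rac1, Rbl2, Slc15a3 and Wipi1). Their highest adjusted p-values ran from 0.053 (Bst2) to 0.25 (Ear2). The median of the T and NK cell list turned positive when saline replicate 1, 2 or 3 or carnosine replicate 2 was left out, with a range of -0.11 to 0.11 over the libraries left out. The ranges for Ly6a (-0.33 to 0.19), Bax (-0.0927 to 0.0977, and 0.12 with the GC and length correction) and Cndp2 (-0.0408 to 0.00991, and 0.00819 with that correction) crossed 0 too. None of these was called, and the cause was not tested. At this depth, 0 counts over a saline group still allow 0.0679 CPM, and over a carnosine group 0.0737 CPM.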

Other observations

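The tests of families, of class II genes, of GC content and length, of one pool and of amount for V segments, of cell shares and of handling were chosen after the result was seen. Of 11 genes tied to the class II major histocompatibility complex, which presents peptides to T cells, 8 rose with carnosine and 3 did not pass edgeR's test, a set chosen after the values were seen and not tested as a group. H2-Aa, H2-Ab1 and Cd74 belong to the B cell list, and Igkc of that list rose from 1126 ± 8.02 to 2002 ± 14.2 CPM (SD, n = 3 each), while Ighm (-1.30 on the log2 scale), Ms4a1 (-3.18) and Blk (-1.03) of the same list fell. The chain genes H2-Aa and H2-Ab1 rose from 100.4 ± 2.06 to 305 ± 1.3 and from 186 ± 9.17 to 477 ± 17.9 CPM (SD, n = 3 each). H2-Eb1 (1.56 ± 0.0396 on the log2 scale, SE), the invariant chain Cd74 (1.42 ± 0.0288) and the class II transactivator Ciita (1.49 ± 0.0766) rose too, as did H2-DMb1 (0.76), H2-DMb2 (0.86) and H2-Eb2 (0.92, a call lost in 8 of 11 alternative settings). H2-DMa (-0.0764), H2-Oa (-0.23) and H2-Ob (0.0579) did not pass edgeR's test, though H2-Oa did without carnosine replicate 1 (-0.42, adjusted p = 0.02, with a range of 0.02 to 0.56 over its alternatives).

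Outside the fixed lists, 180 families of at least 8 tested genes that share the start of their symbol were tested with camera. The 16 Rpl genes not in the ribosomal list passed (0 higher, 10 lower, median log2 fold change -0.32, camera adjusted p = 0.011), and lost the call with an estimated correlation (adjusted p = 0.70). Of 10237 genes over 10 CPM in either group, 236 differed over 2-fold between libraries of a group, and 22 of these were called. Gpx1, which encodes an antioxidant enzyme, had 96.3, 127 and 92.3 CPM in the saline libraries and 620.1, 129.8 and 666 CPM in the carnosine libraries.

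Antibody V segments differed between the groups and were alike within them: of 30 segments that parted the groups, 28 had at least 20 counts in every carnosine library and at most 1 in every saline library, and 2 the reverse. By contrast 0 segments were split in this way between libraries of a group, as one pool of cells behind each group's libraries would give. That cut was chosen after the values were seen, and some segments came near it. Ighv11-1 had 0, 19 and 16 counts in carnosine replicates 1, 2 and 3, and Igkv13-85 had 12, 0 and 0 in the saline ones. One pool per group is therefore not shown, but it is not excluded either. The 3 libraries of a group may thus not be separate biological replicates. A different amount of the same B lineage cells, which the lineage gate should remove, predicts like segment shares, yet the smallest Bray-Curtis distance between the groups was 0.381, against 0.0349 to 0.0543 within them. Reads shared between similar segments would leave the groups alike over subgroups of such segments, yet over 35 subgroups the smallest distance between groups was 0.153, against 0.0145 to 0.0338 within. Whether carnosine itself bears on the segments was not tested, since the pool and the treatment may differ together.

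Immediate early and NF-kB genes were lower with carnosine. With trends in GC content and gene length taken out, the median log2 fold change of both lists was -1.14 (95% bootstrap interval -1.39 to -0.90), which argues against those trends as the whole cause. Fewer monocytes or macrophages, which the lineage gate should remove, would lower their own list as much, but its median lay 1.05 above that of the NF-kB list (0.43 to 1.47). Of its 15 tested members 10 reach 5 CPM in the saline libraries and 3 stand in another list, and Lyz2 was at 96.5 ± 1.25 and 81.5 ± 4.44 CPM (SD, n = 3 each). A difference in handling between the groups, such as the time from marrow to lysis, could also move these genes and cannot be told apart from the treatment: all 28 immediate early genes part the groups without overlap, as do 52.3% of all tested genes (chance gives 10%).

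Megakaryocyte genes were lower and myeloid progenitor genes higher with carnosine, and moving with them were long-term stem cell genes (22 of 33 lower, median -0.78), stromal and endothelial genes (9 of 13 lower, median -1.05) and erythroid genes (13 of 21 higher, median 0.34), 3 lists whose calls by camera were lost with an estimated correlation (adjusted p = 0.051, 0.12 and 0.06). With GC and length trends taken out, the myeloid progenitor median lay 1.84 above that of the stem cell and megakaryocyte lists (1.37 to 2.08), which argues against those trends as the whole cause. A lower share of stem cells with every other cell type raised alike would lift monocyte genes as much, but the myeloid progenitor median lay 1.07 above the monocyte and macrophage median (0.57 to 1.5). Since the lineage gate should remove monocytes, this cannot speak to a lower share of stem cells beside other cells of the gate. More myeloid progenitors within the gate stays open: Cd34, which such cells carry, had a log2 fold change of -0.13 (-0.21 to -0.04 at 2 SE to either side). It did not pass edgeR's test, and its level in both groups could hide a small share. A change within the sorted cells after carnosine, or in their erythroid or stromal share, stays open and was not tested. The sort should leave out erythroid and stromal cells.

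The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.1. The real split gave 3038 genes higher (the highest other split gave 2), 3077 lower (the highest other 2) and 17 lists (the highest other 14), each reached by 1 of the 10 splits. Every other split mixes the groups, so the group difference enters the spread there and lowers the gene calls. These splits still carry part of that difference, and camera called 9 to 14 lists in them. The splits therefore cannot give a rate of false calls for genes or lists.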
